A study of Homo sapiens with 8 samples.

How the data were processed

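The data are RNA-seq gene counts of 8 libraries of sorted human CD3-negative CD56bright NK cells. Per the labels' protocols, frozen blood mononuclear cells were thawed and rested overnight in serum-containing medium without cytokines, stained and sorted, and the sorted cells were cultured in DMSO or ascorbic acid. RNA was extracted with a column kit, libraries were made with the TruSeq RNA v2 kit, which does not mark strand, and sequencing was paired-end on an Illumina NextSeq. The deposited table holds raw counts per gene symbol, not normalized, with a column for each library. Per the submitters' processing notes, FastQC, HISAT2 2.1.0, featureCounts and Subread 1.6.2 were used with genome build GRCh37; the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart. Reads that fit several members of a near-identical family, such as the KIR genes, could be split or lost by the counting, so single KIR genes are given as uncertain beside sums over the family. KIR genes with no row in the table, KIR2DS1 among them, were not analysed here.

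The counts were used as deposited. The table has 57905 rows, of which 0 name no gene, and 0 columns were left unmatched to a sample. There were 244 symbols on more than 1 row (2267 rows, 78 of them tested); such rows were kept apart. Total counts per library lay between 13577475 and 16713569, and the 10 most counted genes held between 5.22% and 5.86% of them. Genes at a few CPM carry more counting error than abundant genes.

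Groups were taken from the treatment in the labels and pairs from the code that the titles of a DMSO and an ascorbic acid library share, read here as the source of the cells. The pairing was checked in the data: deviations from the group means correlated at 0.735, 0.820, 0.688 and 0.836 within pairs, and the highest correlation between a DMSO and an ascorbic acid library of different pairs was -0.16. The first 3 principal components (42.3%, 22.8% and 19.5% of variance) separated pairs, and the fourth (5.73%) separated the groups. On the fourth, pair 3 was parted most widely, with scores of 17.2 for DMSO and -14.7 for ascorbic acid. In the other pairs the scores were 5.41 to 6.73 for DMSO and -7.40 to -6.19 for ascorbic acid. Libraries of a group differed far beyond counting noise (chi-square per degree of freedom between 16.4 and 37.8), and libraries of a pair less so (between 3.84 and 10.3), so none was counted as a duplicate. A check for exchanged libraries, which compared a few sex-linked genes, found 0 that differed from the pair's other library. It could not detect an exchange within a pair, or between pairs alike in these genes. The labels do not say that the libraries of a group come from separate people; if they do not, the p-values measure only the spread between these samples.

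Genes were filtered with edgeR's filterByExpr (12721 kept), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, two-sided, Benjamini-Hochberg adjusted p under 0.05). The fit without pairing was fixed as the main design, and the fit with the pairs as a block as a second result, before the data were examined. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM per group are means over 4 libraries. Changes within a pair are log2 CPM ratios with a prior count of 2. There were 30 gene lists fixed before the data were examined (656 distinct symbols, 648 found in the table); 27 with at least 5 measured members were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The named genes followed a rule fixed in advance: up to 12 rising and 12 falling genes with the smallest adjusted p and the same sign in all pairs in each fit, the measured KIR, TET and DNMT genes, and up to 4 passing members of each list, or the 2 with the smallest p where none passed. Symbols known only as clones and HLA and other highly variable immune genes were skipped (5 called rows), and no Y-linked gene is named. FCGR3A, GZMB, PRF1, GZMK, KLRC1, AHRR, CYP1B1, CD74, S1PR1, S1PR5, ITGB7 and genes named as lying beside a list or the KIR cluster fall outside that rule and were chosen after other results were seen. Some genes covered by these rules are not reported here.

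Alternatives were RLE and upper quartile scaling, no low-count filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma voom, the other pairing choice, leaving out each replicate or pair and the 50 ng/ml pairs alone. Neighbours of the KIR cluster were looked up by gene order in the RefSeq annotation of GRCh38.p14, from which no coordinates are used. All tests ran in R 4.3.3.

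The tests were first run on simulated data made from the means, library sizes and dispersions of the 12721 genes, with 200 genes changed in each of 3 simulations. The paired test recovered 66% of genes changed 1.3-fold and 92% of genes changed 2-fold, with a mean of 19.7 false calls, or 11.1% of the calls. The test without pairing recovered 1.33% and 63%, with 0 false calls. A shifted list was found in 3 of 3 simulations by camera in both fits, and 0 of the 21 lists sharing no gene with it were called. The simulated genes were drawn independently of each other. These runs therefore cannot show how often camera calls a list of correlated genes in error.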

Results

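RNA was sequenced from human natural killer (NK) cells of the CD56bright type, the less mature of the main blood NK subsets, sorted as CD3-negative and CD56bright from thawed blood mononuclear cells. The sorted cells were cultured with ascorbic acid (vitamin C) or with DMSO as the control. There were 8 libraries, 4 per group, and each code in the sample titles occurred once with DMSO and once with ascorbic acid, which gives 4 pairs. The labels put the ascorbic acid of 3 pairs at 50 ng/ml and that of pair 3 at 25 ng/ml. These doses are in the unit the labels give, which is lower than is usual for ascorbic acid in cell culture and could not be checked. The length of the culture is not given in the sources used here. The total count per library lay between 13577475 and 16713569, with a mean of 14699151 ± 801884 (SD, n = 4) for DMSO and 15811112 ± 842727 (SD, n = 4) for ascorbic acid. Of the 57905 rows of the gene table, 12721 passed the low-count filter and held 99.9% of the counts. Levels are given as CPM, counts scaled to the size of the library.

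The comparison asked which transcripts differ between CD56bright NK cells cultured with ascorbic acid and cells cultured with DMSO. The killer cell immunoglobulin-like receptors (KIR), inhibitory and activating receptors for HLA class I that mature CD56dim NK cells carry and CD56bright cells mostly lack, were higher with ascorbic acid. The summed count of the 12 KIR rows was 649 ± 75.2 CPM with DMSO and 974 ± 80.3 CPM with ascorbic acid (SD, n = 4), a mean 1.51-fold difference that ranged from 1.32-fold to 1.66-fold over the pairs. Among single genes, KIR2DS4 rose 2.04-fold, KIR2DL2 1.67-fold and KIR2DL1 1.63-fold, each in 4 of 4 pairs. With 4 pairs, an exact sign-flip test (two-sided) of the sum gave p = 0.125, the smallest that 4 pairs allow.

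In edgeR's quasi-likelihood test with the pairs as a block, 3 of the 8 measured KIR genes passed at adjusted p = 9.96e-06 for KIR2DS4 (log2 fold change 1.03, SE 0.08), 0.00142 for KIR2DL1 (0.71, SE 0.10) and 0.00539 for KIR2DL2 (0.74, SE 0.08). The number was 5 when adjusted over the list alone. KIR3DL1 had a log2 fold change of 1.59 (SE 0.24) and KIR2DL3 1.13 (SE 0.17), with higher values in 4 of 4 pairs, but their adjusted p in edgeR over all genes was 0.147 and 0.106. DESeq2 put both past the threshold, with adjusted p = 1.31e-08 for KIR3DL1 and 9.86e-06 for KIR2DL3. KIR2DL4, the framework receptor that CD56bright cells also express, had a log2 fold change of 0.14 (SE 0.08), KIR3DL2 0.13 (SE 0.13) and KIR3DX1 -0.01 (SE 0.05), none of which passed. The KIR genes are near-identical copies that can share reads, and people differ in the KIR genes they carry, so the split between single KIR genes is uncertain. KIR2DL2 no longer passed without pair 3 (log2 fold change 0.74, edgeR adjusted p = 0.231). In edgeR, 3 further KIR genes passed when a certain pair was left out or the filter was dropped: KIR2DL4 had adjusted p = 0.0196 without pair 2 (log2 fold change 0.25), KIR2DL3 6.16e-12 without pair 2 and 0.000464 with no low-count filter, and KIR3DL1 4.86e-10 without pair 3.

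**Figure D1:**
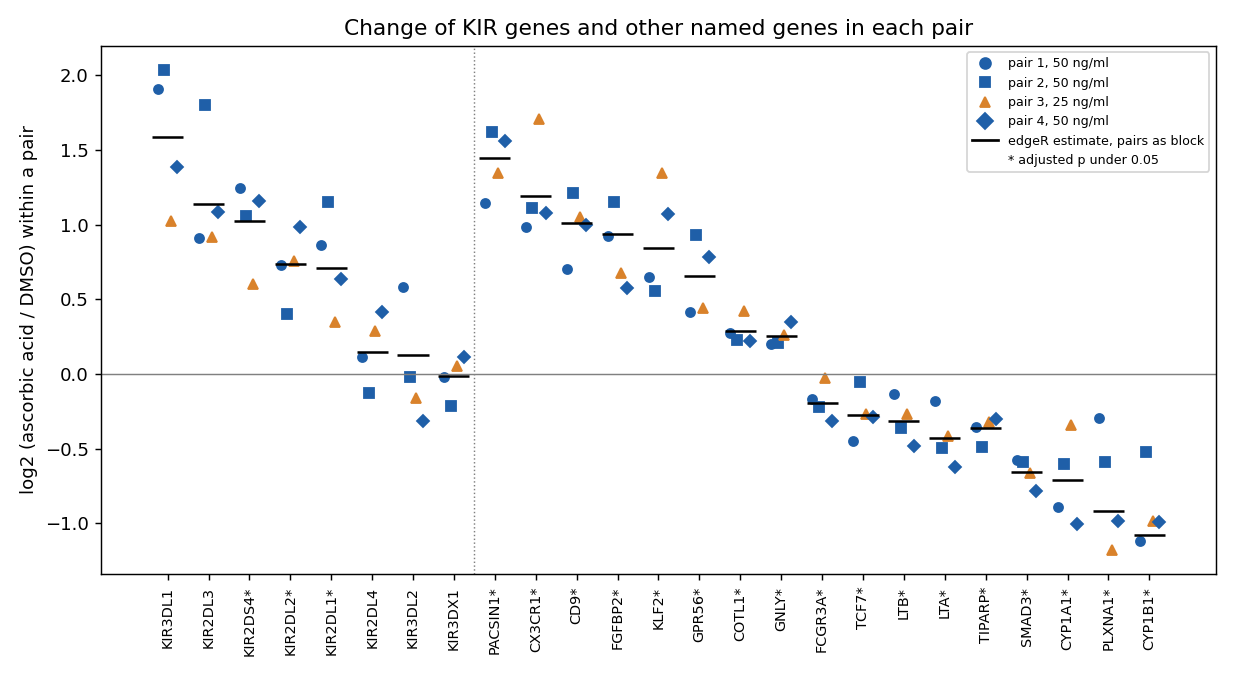
Log2 ratio of ascorbic acid to DMSO within each pair (y axis; log2 CPM with a prior count of 2) for the measured KIR genes (left of the dotted line) and for other genes named in the text; blue symbols are 50 ng/ml pairs, orange triangles the 25 ng/ml pair, black bars the paired edgeR estimates, and asterisks mark adjusted p under 0.05. KIR2DS4 lies above 0 in 4 of 4 pairs with an estimate of 1.03, and KIR3DX1 lies at -0.01.

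Outside the KIR family, CX3CR1, the fractalkine receptor, rose 2.28-fold, from 11.5 ± 14.5 to 25.6 ± 30.8 CPM (SD, n = 4). KLF2, a transcription factor that controls lymphocyte trafficking, rose 1.79-fold, FGFBP2 1.92-fold, and GPR56, an adhesion receptor of cytotoxic lymphocytes, 1.57-fold. PACSIN1, a membrane-bending adaptor protein, had the smallest adjusted p in edgeR (3.95e-07) and rose 2.73-fold, from 5.04 ± 2.46 to 13.9 ± 7.53 CPM. The tetraspanin CD9 rose 2.02-fold, SBK1 1.81-fold, the galectin LGALS3 1.72-fold, and TLR3, a sensor of double-stranded RNA, 1.65-fold. Smaller rises were seen for BCAT1, the cytosolic branched-chain aminotransferase (1.43-fold), AFAP1L2 (1.35-fold) and the chromatin protein HMGA1 (1.24-fold).

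Genes that fell with ascorbic acid included SMAD3, a signal transducer of TGF-beta, which went from a mean of 53.7 to 34.2 CPM (n = 4) with a log2 fold change of -0.65 (SE 0.06). The aryl hydrocarbon receptor targets CYP1A1 (log2 fold change -0.71, SE 0.10) and TIPARP (-0.36, SE 0.04) fell in 4 of 4 pairs. So did LTA and LTB, which encode the lymphotoxins, with log2 fold changes of -0.43 and -0.31. The rule that picked CYP1A1, TIPARP, LTA and LTB asked for the same sign in all pairs. The semaphorin receptor genes PLXNA1 (-0.92) and PLXNA4 (-0.30) fell, as did UBASH3A (-0.60), HIC1 (-0.51), TMEM2 (-0.38), TIE1 (-0.34) and ITM2A (-0.27). Among transcription factors, TCF7, which is higher in CD56bright than in CD56dim cells, had a log2 fold change of -0.28, ZBTB16 of -0.36 and NFIL3 of -0.23, and all 3 passed. TCF7 did not pass without pair 1 (-0.22, edgeR adjusted p = 0.282), without pair 4 (-0.27, 0.0964) or in DESeq2 (-0.28, 0.168).

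In all, 192 genes passed at an adjusted p under 0.05 in the paired edgeR test, 129 higher and 63 lower with ascorbic acid. Of these, 123 were higher and 62 lower in every pair. The changes were small: the median absolute log2 fold change of the called genes was 0.33, 139 of the 192 lay under 0.5, 7 rose more than 2-fold and 1 fell below 0.5-fold. In simulated data, 11.1% of the calls of the paired test were false. The test without pairing, fixed in advance as the main design, passed 0 genes in edgeR (130 at an unadjusted p under 0.05). It passed 0 in DESeq2 (123) and 0 in limma voom (141), and 3 principal components that separate pairs held most of the variance. The paired count fell to 77 without pair 1 and to 100 in DESeq2, 94 of which were among the 192. It rose to 421 with no low-count filter (216 higher, 205 lower), and without pair 4 there were 103 higher and 97 lower, so the excess of higher genes nearly vanished in both.

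**Figure D2:**
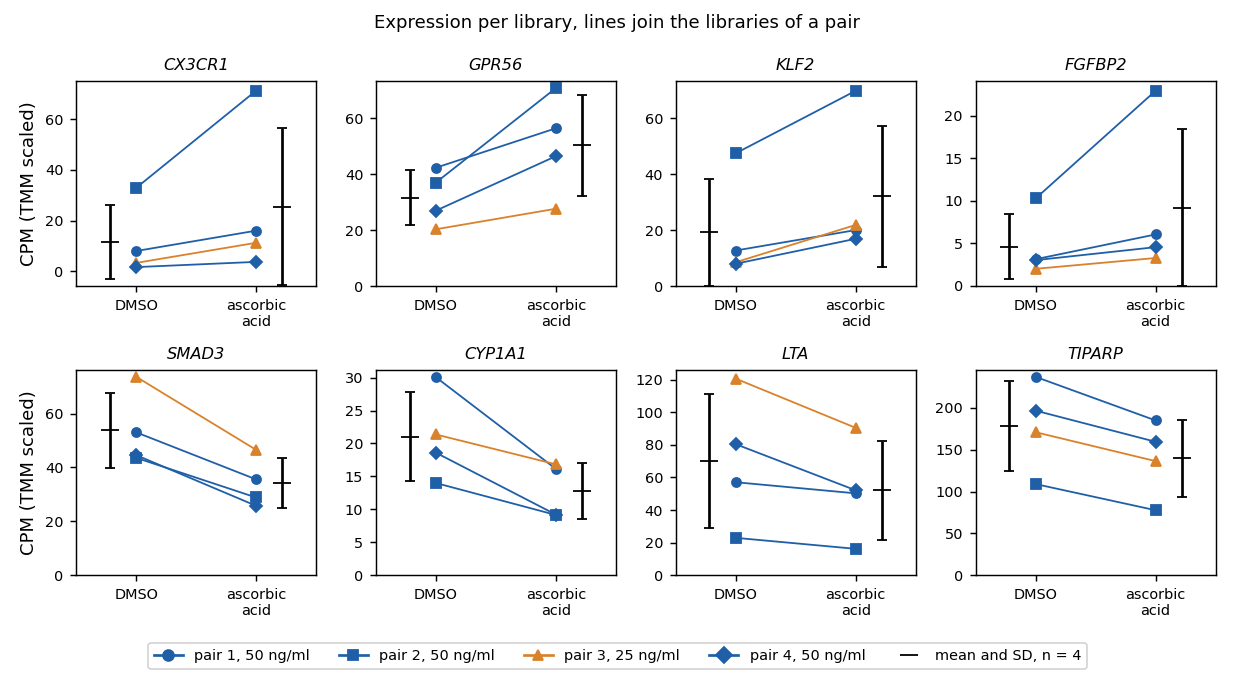
CPM (y axis, scaled by TMM factors) of 8 genes in each library, by group (x axis); lines join the libraries of a pair, and black bars give each group's mean and SD (n = 4). CX3CR1, GPR56, KLF2 and FGFBP2 go up and SMAD3, CYP1A1, LTA and TIPARP go down in each of the 4 pairs, at levels that differ between pairs. All but KLF2 were picked by a rule that asked for the same sign in all pairs.

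Gene lists fixed before the data were examined describe these changes by group. Of 18 measured CD56dim NK markers, 6 rose (CX3CR1, FGFBP2, GPR56, GNLY, GZMH and CHST2) and 1 fell, FCGR3A, which encodes CD16 and had a log2 fold change of -0.19 (SE 0.05, edgeR adjusted p = 0.0411). Adjusted over the list alone, 9 rose and 1 fell. GNLY, the cytotoxic granule protein granulysin, rose 1.19-fold and GZMH, a granzyme, 1.17-fold. GZMB and PRF1, granzyme B and perforin, had log2 fold changes of 0.14 (SE 0.04) and 0.08 (SE 0.04), with edgeR adjusted p = 0.14 and 0.459. Of 20 measured CD56bright markers, 2 rose, among them COTL1 (log2 fold change 0.29), and LTB and TCF7 fell, with 3 higher and 4 lower when adjusted over the list alone. FCGR3A missed the threshold without pair 1 (edgeR adjusted p = 0.217), pair 2 (0.106) or pair 4 (0.236) and in DESeq2 (0.149).

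Of 22 effector molecules, GNLY and GZMH rose and LTA fell (4 rose and 2 fell when adjusted over the list alone). Of 24 NK transcription factors, KLF2 and RUNX3 (log2 fold change 0.21) rose and TCF7, NFIL3 and ZBTB16 fell (3 and 6 when adjusted over the list alone). Of 23 other NK receptors, the checkpoint receptor TIGIT rose 1.18-fold (1 when adjusted over the list alone). In the TGF-beta list of 20 genes, CD9 and LTBP1 (log2 fold change 0.73), a binding protein of latent TGF-beta, rose and SMAD3 fell; adjusted over the list alone, 4 rose and 1 fell.

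Metabolic lists had small upward medians, 0.07 for cholesterol synthesis and 0.09 for glycolysis on the log2 scale. In the cholesterol synthesis list, 3 of 29 measured genes rose: EBP (1.16-fold), the squalene epoxidase SQLE (1.14-fold) and the fatty acid desaturase SCD (1.15-fold), which makes monounsaturated fat rather than sterol; the number was 6 when adjusted over the list alone. In glycolysis, 1 of 22 rose, the enolase ENO1 (1.13-fold), and 9 when adjusted over the list alone. Among 34 targets of the hypoxia-inducible factor HIF, ENO1 and PFKFB4 (1.66-fold), which regulates glycolytic flux, rose, and 7 rose and 1 fell when adjusted over the list alone. Most of these 7 encode enzymes of sugar metabolism, and the HIF and glycolysis lists share genes, ENO1 among them. The shifts of these lists are therefore not independent. In the unfolded protein and amino acid response, 1 of 26 rose, the serine synthesis enzyme PSAT1 (1.37-fold), and 2 when adjusted over the list alone. In the metal response list, 1 of 9 rose, the transferrin receptor TFRC (1.22-fold), and 2 when adjusted over the list alone. Without pair 1, PFKFB4, SQLE, SCD, EBP and ENO1 missed the threshold (edgeR adjusted p = 0.0910, 0.138, 0.0894, 0.140 and 0.348), and without pair 2 the log2 fold change of PFKFB4 was 0.38.

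With limma's camera test, a preset correlation of 0.01 and the pairs as a block, 9 of 27 tested lists were higher and 0 lower. The adjusted p in camera was 1.48e-15 for KIR receptors, 2.59e-09 for CD56dim markers, 3.16e-08 for glycolysis, 4.09e-06 for the unfolded protein and amino acid response, 1.13e-05 for cholesterol synthesis and 1.28e-05 for HIF targets. With an estimated correlation, 0 of the 27 passed: in the same order, the camera adjusted p was 0.0845, 0.0845, 0.249, 0.101, 0.101 and 0.161 with an estimated correlation. Heat shock genes (camera adjusted p = 0.00768), the metal response (0.00853) and proliferation (0.0344) also passed, with adjusted p = 0.668, 0.485 and 0.668 with an estimated correlation. Leaving out a pair ended some camera calls at the preset correlation: heat shock had adjusted p = 0.233 without pair 3 and 0.0647 without pair 4, proliferation 0.277 and 0.0797, and without pair 2 the metal response had 0.248 and HIF targets 0.0667. Calls in the lower direction then appeared in camera for the mitochondrially encoded genes without pair 3 (adjusted p = 3.54e-20) and for the NF-kB and TNF response without pair 1 (0.0449). These smaller fits were not run with an estimated correlation. The fry test, which asks whether a list's genes move on balance in one direction, passed 3 lists with the pairs as a block: KIR receptors and CD56dim markers (fry adjusted p = 0.0265 each) and cholesterol synthesis (0.0455). Without pairing, camera passed 7 lists, and 0 with an estimated correlation or in fry.

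**Figure D3:**
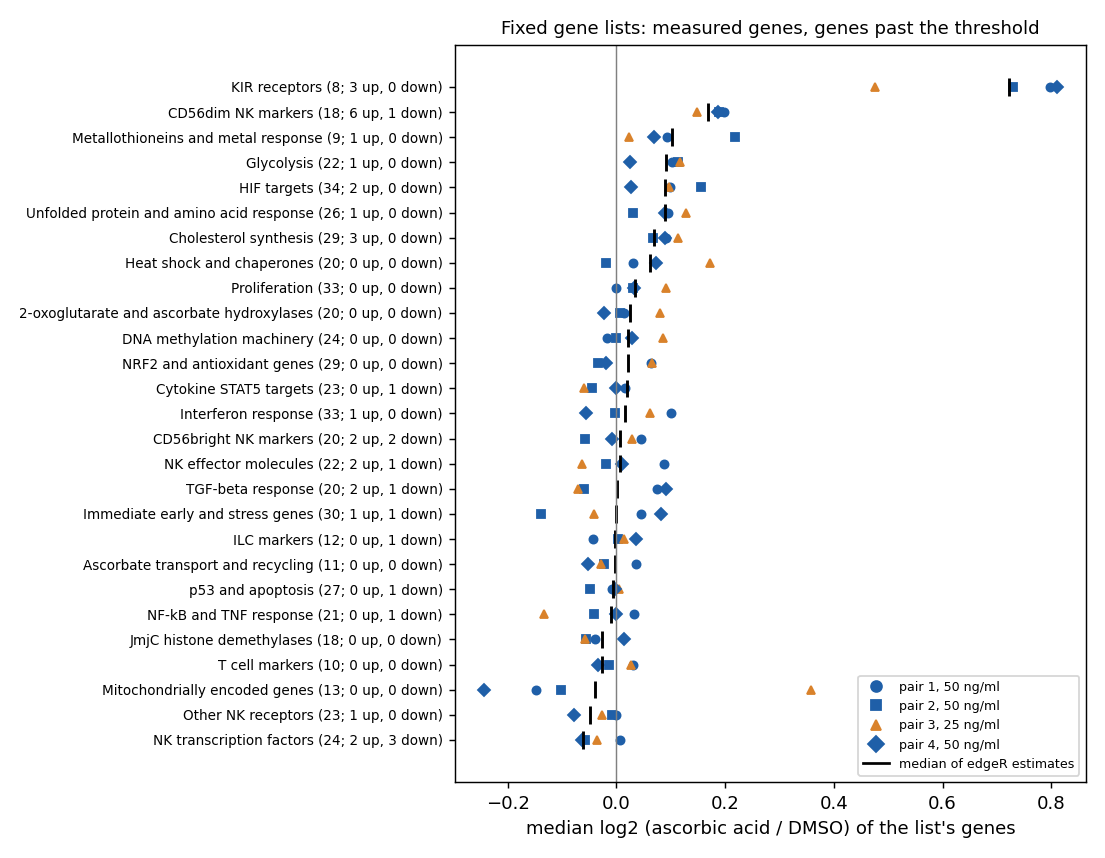
Median log2 ratio of ascorbic acid to DMSO (x axis) over the measured genes of each fixed list (y axis, with the number of measured genes and of genes that passed in each direction); symbols are the 4 pairs and black bars the medians of the paired edgeR estimates. The KIR receptors stand at a median of 0.72 and the CD56dim markers at 0.17.

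Ascorbate is a cofactor of the TET enzymes, which oxidise methylated cytosine, and of other dioxygenases. None of the genes for this machinery passed. TET2 had a log2 fold change of -0.13 (SE 0.06), TET3 -0.12 (SE 0.05), TET1 -0.16 (SE 0.22), DNMT1 0.00 (SE 0.04), DNMT3A 0.15 (SE 0.06) and DNMT3B 0.21 (SE 0.08), with edgeR adjusted p from 0.224 (DNMT3B) to 0.985 (DNMT1). In all, 0 of 24 DNA methylation genes and 0 of 18 JmjC histone demethylases passed, and 0 of each when adjusted over the list alone. Of 20 hydroxylases that use 2-oxoglutarate and ascorbate, 0 passed over all genes, and 1 was higher when adjusted over the list alone, the collagen lysyl hydroxylase PLOD1 (log2 fold change 0.21, SE 0.06). Among 11 genes of ascorbate transport and recycling, 0 passed over all genes; adjusted over the list alone, GLRX (0.15) was higher and the ascorbate transporter gene SLC23A2 (-0.18) lower. Transcript levels do not measure enzyme activity.

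Stress and signalling lists held single changes. NR4A3, an immediate early nuclear receptor, rose by a log2 fold change of 0.68 and DUSP6 had a log2 fold change of -0.18 among 30 immediate early and stress genes (3 and 2 when adjusted over the list alone). The interferon-induced GBP1 rose 1.24-fold, 1 of 33 interferon response genes (2 when adjusted over the list alone). REL (log2 fold change -0.25) fell, 1 of 21 NF-kB and TNF response genes, as did TP53INP1 (-0.45), 1 of 27 p53 and apoptosis genes; each count was the same when adjusted over the list alone. LTA fell as 1 of 23 cytokine and STAT5 targets (3 rose and 2 fell when adjusted over the list alone). Over all genes, 0 of 29 NRF2 and antioxidant genes, 0 of 33 proliferation genes, 0 of 20 heat shock genes and 0 of 13 mitochondrially encoded genes passed; adjusted over the list alone, these lists gave 2 higher and 1 lower, 1 higher, 0 and 0. The mitochondrially encoded genes had a median log2 change of 0.36 in pair 3 and of -0.15, -0.10 and -0.24 in pairs 1, 2 and 4.

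Among markers of other cells that the sort could hold, LTB alone passed over all genes. Summed monocyte and dendritic cell markers were at 4.52 ± 1.23 CPM with DMSO and 3.22 ± 0.955 CPM with ascorbic acid (SD, n = 4). Within pairs, the mean log2 ratio of this sum was -0.50 (SD 0.12), below 0 in every pair (range -0.66 to -0.41). Summed platelet and erythroid markers were at 0.233 ± 0.103 and 0.273 ± 0.143 CPM. B cell markers summed to 31.3 ± 5.25 and 32.2 ± 2.31 CPM. T cell markers summed to 1063 ± 138 and 1055 ± 147 CPM, mostly from CD8A, CD3E and TRBC2, which NK cells also transcribe, while TRAC averaged 5.90 CPM. Of the 10 T cell, 3 B cell and 2 monocyte and dendritic cell markers measured, 0 passed; adjusted over the list alone, 1 monocyte marker, VCAN, was lower (log2 fold change -0.57). The platelet and erythroid list had 0 measured genes. Of 12 markers of other innate lymphoid cells, 1 fell, LTB, with 1 higher and 2 lower when adjusted over the list alone.

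The sum of the 12 KIR rows was 1.55-fold higher in the 25 ng/ml pair, inside the range of the other pairs. The median log2 change of the 8 measured KIR genes was lowest in that pair (0.47, against 0.73 to 0.81). So was the ratio of a sum of the 6 measured KIR genes other than KIR2DL4 and KIR3DX1, chosen after KIR counts had been seen (1.73-fold, with a mean of 2.02-fold and a highest of 2.21-fold). Of 197 genes that passed in the 3 pairs at 50 ng/ml alone, 180 (91.4%) had the same sign in the 25 ng/ml pair, with a median log2 change in the called direction of 0.28 in that pair and 0.32 in the others. Across 12721 genes, the log2 changes of any 2 pairs correlated weakly, with a mean Pearson r of 0.124 (range 0.0895 to 0.173) and a mean Spearman rho of 0.129 over 6 combinations. With the sign of 1 or more pairs flipped, the highest mean r was 0.0194. Flipping signs must lower a mean of correlations that are all positive, so this value is no reference for chance. Genes are not independent replicates, so no p is given. The 25 ng/ml dose has 1 pair, so no difference between doses was tested.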

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

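Of the tests in this part, the one of the summed KIR count was chosen only after the result was seen. Among 101 sets of 4 pair or library values, 4 held a value far from the other 3, where about 5.05 would be expected by chance. PSAT1 had a log2 change of 0.73 in pair 2, against 0.33 to 0.36 in the other pairs. DNMT3B had 0.38 in pair 4, against 0.16 to 0.18. TET2 had -0.32 in pair 3, against -0.09 to -0.05. The mitochondrial gene MT-CO1 was higher in pair 3 (0.33) and lower in the others (-0.24 to -0.23), as was the median of the 13 mitochondrially encoded genes (0.36, against -0.24 to -0.10).

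The higher KIR transcripts were set against 3 technical explanations. Reads moved between near-identical KIR genes would leave the family's sum in place, but the sum was higher by 0.59 on the log2 scale. Shared reads that the counting drops could change the sum, and the counting settings are not given. The sum therefore speaks only to reads reassigned within the family. More CD56dim cells in the ascorbic acid libraries would bring CD16 transcripts, but FCGR3A had an upper 95% limit of -0.10. Of the 18 measured CD56dim markers, 6 rose and 1 fell, with a median log2 fold change of 0.17. Among them CX3CR1 (1.19), FGFBP2 (0.94) and GPR56 (0.65) rose by more than the KIR sum. A fall of FCGR3A within each cell would hide added CD56dim cells, so this comparison cannot exclude them. A rise of the whole chromosome region would lift its neighbours, but the 14 measured genes nearest the KIR cluster had a median log2 fold change of -0.0417, and 1 of them, LILRA2 (0.28), passed. Outgrowth or survival of a subset with more KIR transcripts within the CD56bright gate would also raise the sum. None of these 3 comparisons addresses it, and it was not tested. A response of KIR transcription to ascorbic acid may be considered as a hypothesis beside it, found and tested on the same libraries.

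The rise of CX3CR1, FGFBP2 and GPR56 could also reflect more CD56dim cells. All 3 of GZMB, PRF1 and FCGR3A, which those cells carry at high levels, had upper 95% limits (0.23, 0.17 and -0.10) under the smallest change of the 3 genes (0.65). GZMK (0.21) and KLRC1 (0.04), which are higher in CD56bright cells, did not pass in either direction, though GZMK passed as higher with no low-count filter (edgeR adjusted p = 0.00319) and without pair 4 (0.0288). GZMB and PRF1 averaged 2056 and 3399 CPM, a level at which a small share of added cells would not be seen. FCGR3A (131 CPM) therefore carries this argument, which holds only if its level within each cell did not fall. That was not tested. Outgrowth or survival of a subset within the CD56bright gate was not tested and stays open.

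Other splits of the samples were counted. Without pairing, the real count of genes was 0, which each of the 35 splits of the 8 libraries reaches, so the splits say nothing about it; the highest other split gave 427. The 3 splits that keep pairs together gave 293, 31 and 427, which points to a structure of the samples by pair. For lists without pairing, 13 of 35 splits gave at least the real 7 (highest other 12), but the other 12 of these part 0 or 2 pairs and so carry differences between pairs. The 7 other splits that part all 4 pairs, as the real one does, gave 0 to 3 lists without pairing, and these 8 are too few for a share under 0.05. With the pairs as a block there are the same 8 splits, again too few for a share under 0.05: for genes 1 of 8, the real one, reached 192, and the highest other gave 1. For lists 3 of the 8 reached the real 9, and the 7 other splits gave 3 to 9. Camera at the preset correlation thus called lists in every split, so its count of lists does not set the real grouping apart.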

How the results depend on the processing

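The alternative that adds up rows with the same symbol was chosen after seeing the data; it left the paired count at 192. Without pairing the count of genes was 0 in every alternative that kept the design, and 192 with the replicate block (129 higher, 63 lower), because the block removes the spread between pairs; lists went from 7 to 9 with that block. The paired count was 421 with no low-count filter (216 higher, 205 lower), 100 in DESeq2 (69 and 31) and 0 with no replicate block; it lay between 177 and 201 for the other scalings, the stricter filter and limma voom. Leaving out a pair gave 77 to 201 genes (53 to 133 higher, 24 to 97 lower). The lowest came without pair 1, with 73 of the 77 among the 192, and 97 lower genes came without pair 4. The cause of these moves was not tested. All 192 kept their direction in DESeq2, voom and both scalings. With an estimated correlation 0 lists passed with or without pairing; fry passed 0 without pairing and 3 with it. Leaving out a replicate gave 6 to 7 lists without pairing and 7 to 10 with it, but not always of the same lists: with pairing, heat shock, proliferation, the metal response and HIF targets each lost the call in at least 1 fit. The mitochondrially encoded genes passed as lower without pair 3 (camera adjusted p = 3.54e-20) and the NF-kB and TNF response without pair 1 (0.0449), while NK effector molecules passed as higher without pair 3 (0.0348) and the interferon response without pair 4 (0.0483). The mean correlation between pairs was 0.242 for genes of at least 10 CPM, where counting error is smaller. Of 51 named or tested genes that passed, 19 lost the call without pair 1, 9 without pair 2, 6 without pair 3, 9 without pair 4, 12 in DESeq2 and 2 in voom; all 51 lost it with no replicate block. Genes short of the threshold gained the call in edgeR in some of these fits: PLOD1, GZMK, KIR2DL3 and S1PR1 with no low-count filter, PLOD1, KIR2DL3, KIR2DL4 and AHRR without pair 2, KIR3DL1, LEF1, MT-ATP8 and MT-CO1 without pair 3, and GZMK without pair 4. Values near 0 changed sign: KIR3DL2 ranged from -0.13 to 0.27, CD79B from -0.0499 to 0.0800, KIR3DX1 from -0.0548 to 0.0452, DNMT1 from -0.0332 to 0.0344 and ITGB7 from -0.0534 to 0.0400 when a pair was left out. With no replicate block KIR3DX1 was at 0.0012 and ITGB7 at 0.0088. None of these passed in any of these fits.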

Other observations

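The tests of AHRR and CYP1B1 and of S1PR1, S1PR5 and ITGB7 were chosen after the changes they follow up were seen, but before their own values were displayed; S1PR5 is also a member of the fixed CD56dim list, whose count of higher genes had been seen by then. Among called genes outside the fixed lists, several encode proteins of the cytoskeleton, adhesion and migration. The selectin ligand SELPLG (log2 fold change 0.25), the sphingosine phosphate receptor S1PR4 (0.31), vinculin (VCL, 0.21), the actin regulator DSTN (0.28), the calcium-binding S100A4 (0.26), annexin ANXA5 (0.38) and the galectin LGALS1 (0.18) rose. CD74, the invariant chain of HLA class II, rose by a log2 fold change of 0.20 (SE 0.05, edgeR adjusted p = 0.0227) and lost the call without pair 1 (0.277) or pair 4 (0.0848). EPAS1, which encodes HIF-2 alpha, had a log2 fold change of -0.44, and the glucocorticoid receptor gene NR3C1 of -0.19. These genes were picked after their values were seen, and no enrichment of such groups was tested.

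Lower activity of the aryl hydrocarbon receptor may account for the fall of CYP1A1 and TIPARP. The hypothesis predicts a fall of its other targets AHRR and CYP1B1. AHRR had a log2 fold change of -0.57 (SE 0.28, lower in 4 of 4 pairs, edgeR adjusted p = 0.553) and CYP1B1 of -1.08 (SE 0.22, lower in 4 of 4 pairs, adjusted p = 0.00948). CYP1B1 lost the call without pair 1 (adjusted p = 0.114) or pair 4 (0.0595). AHR itself had a log2 fold change of -0.01. CYP1B1 fell as the hypothesis predicts. AHRR met the bound set for it, a negative upper 95% limit (-0.02), but was far from the threshold in edgeR with all pairs. Its fall is therefore not shown, and the hypothesis stays open.

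Higher activity of KLF2 may accompany the rise of its transcript. Of 3 further KLF2 targets, 2 had a lower 95% limit above 0: S1PR1 (log2 fold change 0.28, SE 0.09, edgeR adjusted p = 0.158) and S1PR5 (0.43, SE 0.16, 0.259), each higher in 4 of 4 pairs. Neither passed over all genes, except S1PR1 with no low-count filter (adjusted p = 0.0379). ITGB7, at -0.01 (SE 0.05), did not follow. The bound set for the hypothesis asked for 2 of the 3 genes and is met only with S1PR5, which is part of the CD56dim pattern and no independent test, so the hypothesis stays open.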
